A study of Mus musculus with 504 samples.

How the data were processed

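The study sorted mammary tumour cells from 2 lines of MMTV-PyMT mice, in which the polyoma middle T oncogene drives breast tumours. Both lines carried a reporter that labels tumour cells with mCherry through a mammary Flp recombinase and switches them for good to GFP once a tamoxifen-activated Cre recombinase acts. In the Tnc-CreERT2 line the Cre was driven by Tnc, which encodes the matrix protein tenascin C and serves the study as a mark of a partial epithelial-to-mesenchymal transition (EMT). In the Cdh2-CreERT2 line it was driven by Cdh2, which encodes N-cadherin and serves as a mark of a full EMT. GFP therefore marks tumour cells that went through such a state at some time after tamoxifen, including any that later returned to an epithelial state. Per the labels, mice received 2 mg of tamoxifen 2 times a week from week 9 until tumours were taken at week 13 or 14.

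Cells were gated on both colours and on EpCAM, a surface protein of epithelial cells. The populations of mCherry-positive cells were P18 (mCherry high, EpCAM high), P17 (EpCAM high) and P05 (EpCAM negative). Double-positive cells formed P22 (EpCAM high), and GFP-positive cells formed P09 and P16 (both EpCAM medium, with GFP high in P09), P10 (EpCAM low) and P15 (EpCAM negative). The gate of P09 is that of the labels of its libraries. The series description gives that gate under the number P18 and lists none under P09, so what P09 stands for is less certain than for the other populations. Each library held 5 cells pooled in a well and was made with the Smart-seq2 protocol, which copies full-length polyadenylated RNA without molecular identifiers.

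The deposited table holds raw counts of reads per gene for 504 wells, per the labels and as whole numbers in the values: 487 with cells and 17 empty. The submitters' processing notes name the mouse build mm10 and the tools STAR, SAMtools, featureCounts and Subread. Their versions and settings are not given in the sources used here, and nor is whether counting took the strand into account, so that reads of genes overlapping on opposite strands (Plet1 and Plet1os, for example) may be shared. The table lists 55450 gene identifiers, of which 55450 were matched to symbols and coordinates of GENCODE M21 on GRCm38, the assembly behind mm10. It lists 0 reporter or transgene sequences, so GFP, mCherry and Cre transcripts could not be measured. 108 symbols are shared by several identifiers. No library duplicated another.

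The deposited labels mark 335 libraries as having passed quality control and 152 as having failed, and those that passed were used. Their totals ranged from 313655 to 27849014 counts. In the Tnc-CreERT2 line they numbered 55 for P18 (3232190 to 13414012 counts), 50 for P22, 48 for P09, 26 for P16 (491170 to 10001459), 25 for P10 (313655 to 9524984), 12 for P15 (508631 to 7293999), 32 for P05 (1046829 to 6752810) and 11 for P17 (329160 to 11219091). In the Cdh2-CreERT2 line they numbered 50 for P18 (320085 to 20776715), 16 for P15 (453079 to 27849014) and 10 for P05. Cdh2-CreERT2 P17 cells, which the study's description mentions, were not analysed here, as no such sample is listed.

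The animal was taken as the replicate (5 of each line), since the pools of an animal are not independent. Counts of the libraries that passed were summed per animal and population, giving 43 sums, of which 2 rest on 1 library: P15 of animal TENA2524 and P16 of animal TENA2483. Comparisons within a line were fitted jointly in edgeR 4.0.16 (TMM factors, filterByExpr by population, robust quasi-likelihood F test) with the animal as a block, over 33768 genes. Comparisons between lines used the sums of the population concerned without a block (17878 genes for P18 and 14028 for P15). P values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 are called. Levels are CPM of a sum (counts per 1e6 counts times its TMM factor, 0.57 to 2.528), given as the mean ± SD over animals. CPM of single libraries are without factors, and so are the bounds and ratios below. Fold changes are fitted log2 values ± SE. Where a population had 0 counts of a gene, the fold is given as a bound with 3 counts over that population, and where it had 1 to 3 counts, as the log2 ratio of pooled counts with its 95% exact binomial interval. Such intervals and bounds cover counting error only, since reads are not independent molecules.

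Beside the called genes, 25 gene lists were tested with camera in limma 3.58.1 on voom values of the same sums, with a preset correlation between genes of 0.01 and adjustment over all 370 pairs of a list and a comparison. They cover epithelial, mesenchymal, partial EMT, collagen and matrix, contractile, basal, luminal, milk, cell cycle, interferon response, MHC class I, MHC class II, hypoxia and glycolysis, TGF-beta response, immediate early and heat shock, and mitochondrial genes, EMT transcription factors, and markers of fibroblasts, pericytes, endothelium, macrophages, lymphocytes, neutrophils, adipocytes and erythrocytes. Epcam was kept out of the lists because the gates used it. The lists overlap: Acta2, for example, is in the contractile and the basal list. Of the 370 pairs 119 passed, and 16 of these also passed with a correlation estimated from the data. In what follows a list is called higher or lower where it passed with the preset correlation, and the adjusted p with an estimated correlation stands beside it. Camera compares a list with all other genes, whose median log2 fold change (given per comparison) was away from 0 by over 0.1 in several comparisons. Counts of list members that passed after adjustment over the list alone are given beside those over all genes. Fry was run on the same lists as a check.

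The groups, comparisons, tests, lists, alternative settings and the rule for naming genes were set before the data were examined. The rule names Epcam, Tnc and Cdh2 in each comparison. Among called genes with an average of at least 4 log2 CPM and the same direction in every animal that has both populations, it then takes the 8 largest and the 8 most negative fold changes in the comparisons of P15, P05, P10 and P22 with P18, of P15 with P05 and of Cdh2-CreERT2 P15 with P18, and 4 of each in the others. Between lines the direction condition was that the animals of the 2 lines do not overlap. It adds up to 4 called genes per list with the smallest adjusted p, and passes over symbols made of Gm or Rik numbers or ending in -ps. List members given as examples without being called, and Gm26917, were chosen after their values were seen.

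The animal block was checked on residuals over 12493 genes. The pairing comes from the labels, which name the animal of each library. Sums of the same animal correlated with a median r of 0.062 over 105 pairs (41 above 0.1), and sums of different animals with -0.01 over 413 pairs (14 above 0.1). The procedure was tested on simulated data with the same sums and 50 changed genes of 7295 per fold. Against P18, at log2 folds of 1, 2, 3 and 4, it recovered 0, 10, 46 and 76 percent of changed genes in P05. The shares were 0, 0, 12 and 54 in P15 and 0, 0, 10 and 24 in Cdh2-CreERT2 P15. False calls were 3 in P15 and 0 in the other simulated comparisons, and 0 or 1 of 24 unchanged lists per comparison had an unadjusted p below 0.05. How correlated genes or more variable sums fare stays open.

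Alternative settings were the RLE factors, DESeq2 1.42.0 with its own size factors, no filter, all libraries whatever their quality label, at least 3 libraries per sum (40 sums), equal weight of libraries (limma-trend on log2 of CPM + 1), voom with sample quality weights, single libraries as samples (voom with duplicateCorrelation on the animal), the populations of a comparison alone, no animal block, and leaving out each animal in turn. After the data had been seen, 3 were added: without the 25 libraries at 10 CPM or more of Ptprc (CD45, carried by leukocytes), a filter of 10 CPM in at least 3 sums, and quality weights in fits of the compared populations alone. Work was done in R 4.3.3 with statmod 1.5.0 and the package data.table (1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Sequencing lane and line go together except for animal TENA2524, whose libraries ran with those of the Cdh2-CreERT2 animals, so lane and line cannot be told apart. Cdh2-CreERT2 P05 came from 1 animal and is given as values.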

Results

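In the Tnc-CreERT2 line Epcam transcripts were lowest in the populations sorted without surface EpCAM. Epcam (chromosome 17, 87635979 to 87651129, GRCm38) averaged 4572 ± 1045 CPM (SD, n = 5 animals) in mCherry-high P18 cells, 1577 ± 1704 (n = 4) in EpCAM-low P10 cells. It averaged 229 ± 336 (n = 5) in mCherry-positive, EpCAM-negative P05 cells (75.4 without library R5 of TENA2517). In GFP-positive, EpCAM-negative P15 cells it averaged 43.8 ± 62.6 (n = 3; 7.97 without the library of TENA2524). EpCAM-high P17 (2581 ± 1685, n = 3) lay no higher than the EpCAM-medium P09 (2991 ± 1292, n = 5) and P16 (2591 ± 1342, n = 4). Vim, which encodes the intermediate filament of mesenchymal cells, stood at 9.15 ± 5.72 CPM in P18, 766 ± 398 in P05 and 374 ± 385 in P15. Tnc (chromosome 4, 63959785 to 64047015), the driver of the GFP switch in this line, averaged 48.4 ± 53.3 CPM in P05 (22.17 without library R8 of TENA2524) and 1.55 ± 1.88 in P18, higher in 4 of 5 animals. The 22.5 ± 39.0 of P15 come from 1 of 12 libraries (R3 of TENA2483) and are 0 without it, and P15 was higher than P18 in 1 animal and lower in 2. Tnc passed in no comparison. The median number of genes detected per library was 14140 in P18, 7587 in P05 and 7327 in P15.

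**Figure D1:**
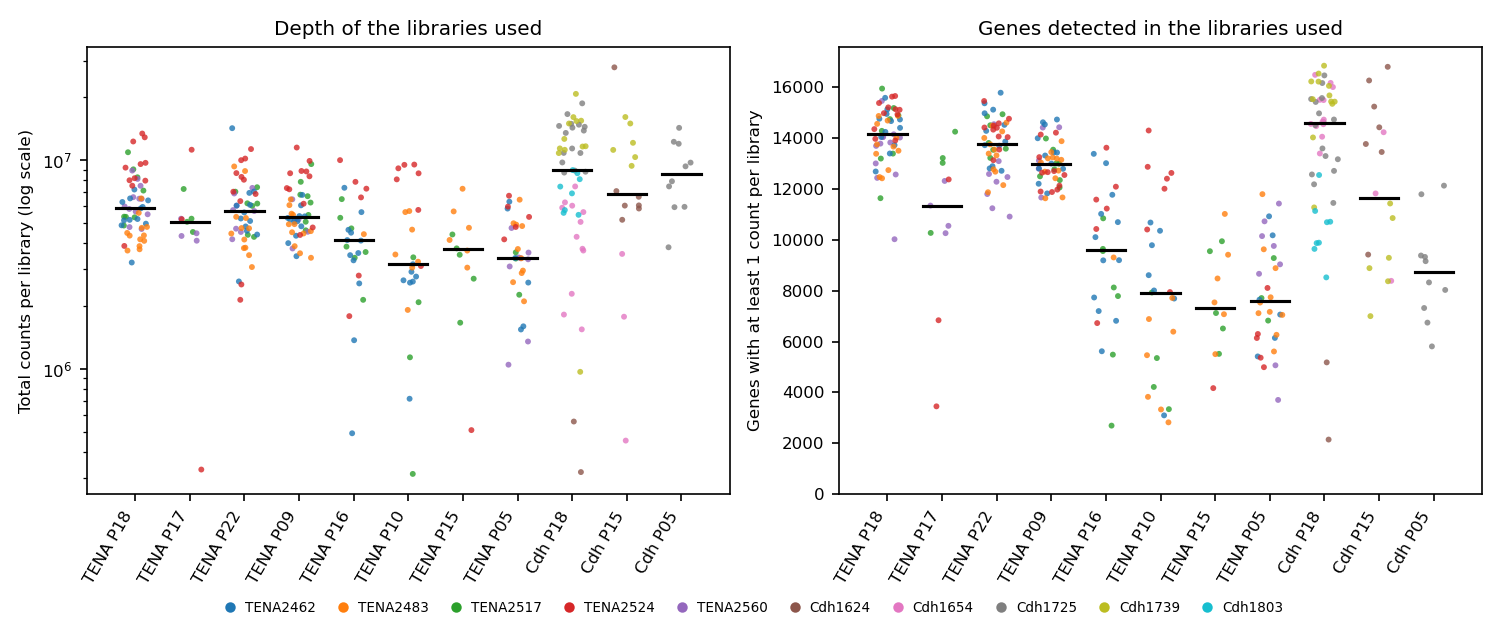
Counts per library and genes detected per library in each population, one point per 5-cell library that passed quality control, with the median as a black line. Median genes detected lie at 14140 in Tnc-CreERT2 P18 and at 7327 in P15 of the same line.

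GFP-positive cells without surface EpCAM (P15) lacked the transcripts of epithelial junctions and keratins that filled P18 cells. Krt8, a keratin of simple epithelia, averaged 4104 ± 1332 CPM in P18 (n = 5 animals) and left 1 read in all 3 P15 sums, a log2 ratio of -17.43 (95% interval -22.73 to -14.95; edgeR adjusted p = 0.0043). The tight junction genes Cldn4 and Cldn7 had 0 reads in P15, with log2 fold changes of -15.22 or lower and -13.63 or lower (adjusted p = 0.0141 and 0.0019). Cldn3, next to Cldn4 on chromosome 5 (134986214 to 134987472 and 134945119 to 134946934), left 1 read (log2 ratio -15.67, interval -20.97 to -13.19, adjusted p = 0.000248). Plet1, which encodes a surface protein of epithelial progenitor cells, went from 6316 ± 1291 CPM to 0 reads (log2 fold change -16.48 or lower, adjusted p = 0.000107). Plet1os (-15.01 or lower) overlaps it on chromosome 9 (50488795 to 50507823, with Plet1 at 50494525 to 50505482) and also had 0 reads. In all, 246 genes were called in P15 against P18, 67 higher and 179 lower, while the median log2 fold change of all genes was -0.61. RLE scaling gave 136 higher and 135 lower, so the excess of lower genes depends on the scaling.

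Of the 32 epithelial genes, 13 were called lower and 29 were lower when adjusted over the list alone. The list had a median log2 fold change of -12.25 (-9.16 with genes at 0 reads placed at their bound) and was called lower by camera (adjusted p = 2.63e-27, and 0.0354 with estimated correlation). Ehf, an epithelial ETS transcription factor, had a log2 fold change of -9.26 ± 1.25 (adjusted p = 0.000248). That of Spint2, an inhibitor of membrane serine proteases, was -7.70 ± 1.12 (adjusted p = 0.000512). Also lower were Wfdc18, a secreted protein with a whey acidic protein domain (-16.04 ± 2.23), Krt7 (-12.14 or lower), Bglap2 (-10.24 or lower) and the growth factor gene Tgfb2 (-6.19 ± 1.38). Among 17 milk genes Muc15 was called lower (-11.57 or lower) and 8 were lower when adjusted over the list alone. The list was lower (median -8.51, -3.23 with bounds, adjusted p = 5.33e-05, and 0.322 with estimated correlation). No interferon response gene was called, and 1 was higher and 5 lower over the list alone. The list was lower (median -4.04, -3.74 with bounds, adjusted p = 1.82e-05, and 0.404 with estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, had 0 reads in P15 and 18.2 ± 5.77 CPM in P18. Mitochondrial RNA was lower with a median of -1.52 (5 of 9 lower over the list alone, adjusted p = 0.000271, and 0.44 with estimated correlation). Genes of hypoxia and glycolysis were lower by a median of -0.75 (adjusted p = 0.0051, and 0.593 with estimated correlation). TGF-beta response genes were lower by -0.82 (adjusted p = 0.00872, and 0.302 with estimated correlation).

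The genes called higher in P15 included several that leukocytes carry. Fcer1g, the shared gamma chain of Fc receptors, averaged 1043 ± 847 CPM against 0.0145 ± 0.0325 (log2 fold change 15.23 ± 3.04, adjusted p = 0.0304). Laptm5, a lysosomal protein of blood cells, averaged 732 ± 679 against 0.0888 ± 0.199 (13.12 ± 3.16, adjusted p = 0.0458). The mannose receptor gene Mrc1 averaged 40.2 ± 33.4 CPM against 1 read in P18 (log2 ratio 13.82, interval 11.34 to 19.12, adjusted p = 0.0304). Apoe, a lipid carrier that macrophages secrete, reached 9315 ± 8286 CPM (9.20 ± 2.27, adjusted p = 0.0485). Of 16 macrophage markers 3 were called higher and 13 were higher over the list alone. The list was higher (median 10.94, 10.99 with bounds, adjusted p = 4.27e-06, and 0.44 with estimated correlation). Ptprc (CD45) stood at 141 ± 128 CPM against 0 reads (adjusted p = 0.052). It was at 10 CPM or more in 12 of the 12 P15 libraries, none of which held Krt8 at that level. MHC class II genes were higher by a median of 6.93 (6 of 7 over the list alone, adjusted p = 0.0353, and 0.596 with estimated correlation). Lymphocyte markers were higher by 4.69 (1 over the list alone, adjusted p = 0.000107, and 0.302 with estimated correlation).

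Mesenchymal and matrix genes were higher as lists, though few libraries carried them. Of the 12 P15 libraries, all with Ptprc at 10 CPM or more, 1 held Col1a1 and 4 held Acta2 at that level. Among 26 mesenchymal genes 2 were called higher, Lox and Fbn1. Over the list alone 9 were higher and 1 lower (median 5.24, 5.07 with bounds, adjusted p = 0.00776, and 0.158 with estimated correlation). Lox, which crosslinks collagen, was at least 12.05 higher on the log2 scale (adjusted p = 0.0329). Fbn1, the microfibril protein fibrillin, had a log2 ratio of 12.52 (interval 10.67 to 15.57, adjusted p = 0.0492). Of 27 collagen and matrix genes 6 were called higher, 15 higher and 1 lower over the list alone (median 7.17, adjusted p = 0.0301, and 0.593 with estimated correlation). They included the proteoglycan Bgn (12.70 ± 2.57), Col5a2 (7.76 ± 1.72), Col6a2 (at least 11.91) and Lum (at least 12.17, with reads in 1 of 3 animals). Islr, a fibroblast marker, was at least 9.67 higher. Smooth muscle actin Acta2 (8.91 ± 1.84) and the signalling gene Wnt4 (log2 ratio 9.64, interval 8.07 to 11.92) were called with 2 animals higher and 1 lower. Acta2 was at 2.69 (adjusted p = 0.533) without TENA2524, and lost its call without TENA2462 or TENA2560 (0.0649 and 0.0748). The lists of EMT transcription factors (median -3.15, 0.87 with bounds, mean -0.81, tested direction up, adjusted p = 0.949), contractile (1.29, adjusted p = 0.72) and basal genes (1.11, adjusted p = 0.985) did not pass. Neither did the luminal list (-2.86, -1.67 with bounds, adjusted p = 0.0561) or the fibroblast list (0.93, 2 genes called, adjusted p = 0.217).

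P15 of animal TENA2524 is 1 library of 508631 counts. Without that animal Rbm15, an RNA-binding protein, went from 5.49 ± 1.00 to 1.26 (adjusted p = 0.00648 and 0.556). Hnrnpa1, a splicing factor, went from 4.42 ± 0.82 to 0.99 (adjusted p = 0.00811 and 0.543). Krt8 lost its call (0.081) but not its fitted log2 fold change (-17.24 with and -17.38 without TENA2524). Other genes named by the rule were Rasa4, a Ras GTPase activator (1024 ± 1731 CPM, with 3022 in TENA2524), Mbnl1, a splicing regulator (280 ± 408), and Rnase4 (211 ± 174). Without TENA2524 they lost their calls (adjusted p = 0.239, 0.506 and 0.205), and their log2 fold changes went from 13.10, 5.20 and 8.05 to 11.76, 1.92 and 6.16. Of the 32 named called genes 7 (Plet1, Plet1os, Cldn7, Wfdc18, Ehf, Cldn3 and Spint2) passed whichever animal was left out. The count of 246 fell to 61 without TENA2462, 127 without TENA2517, 42 without TENA2524 and 76 without TENA2560, and was 409 without Cdh1624, which shares the fit. DESeq2 called 4941 genes. The mesenchymal call was lost without TENA2483 (adjusted p = 0.0809). So were that of collagen and matrix without TENA2483 (median 1.90, adjusted p = 0.494) or Cdh1624 (0.0642) and that of MHC class II without TENA2483, TENA2517 or Cdh1624 (0.324, 0.127 and 0.0612). The hypoxia and TGF-beta calls were lost without TENA2524 (0.17 and 0.159) or Cdh1725 (0.134 and 0.202).

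**Figure D2:**
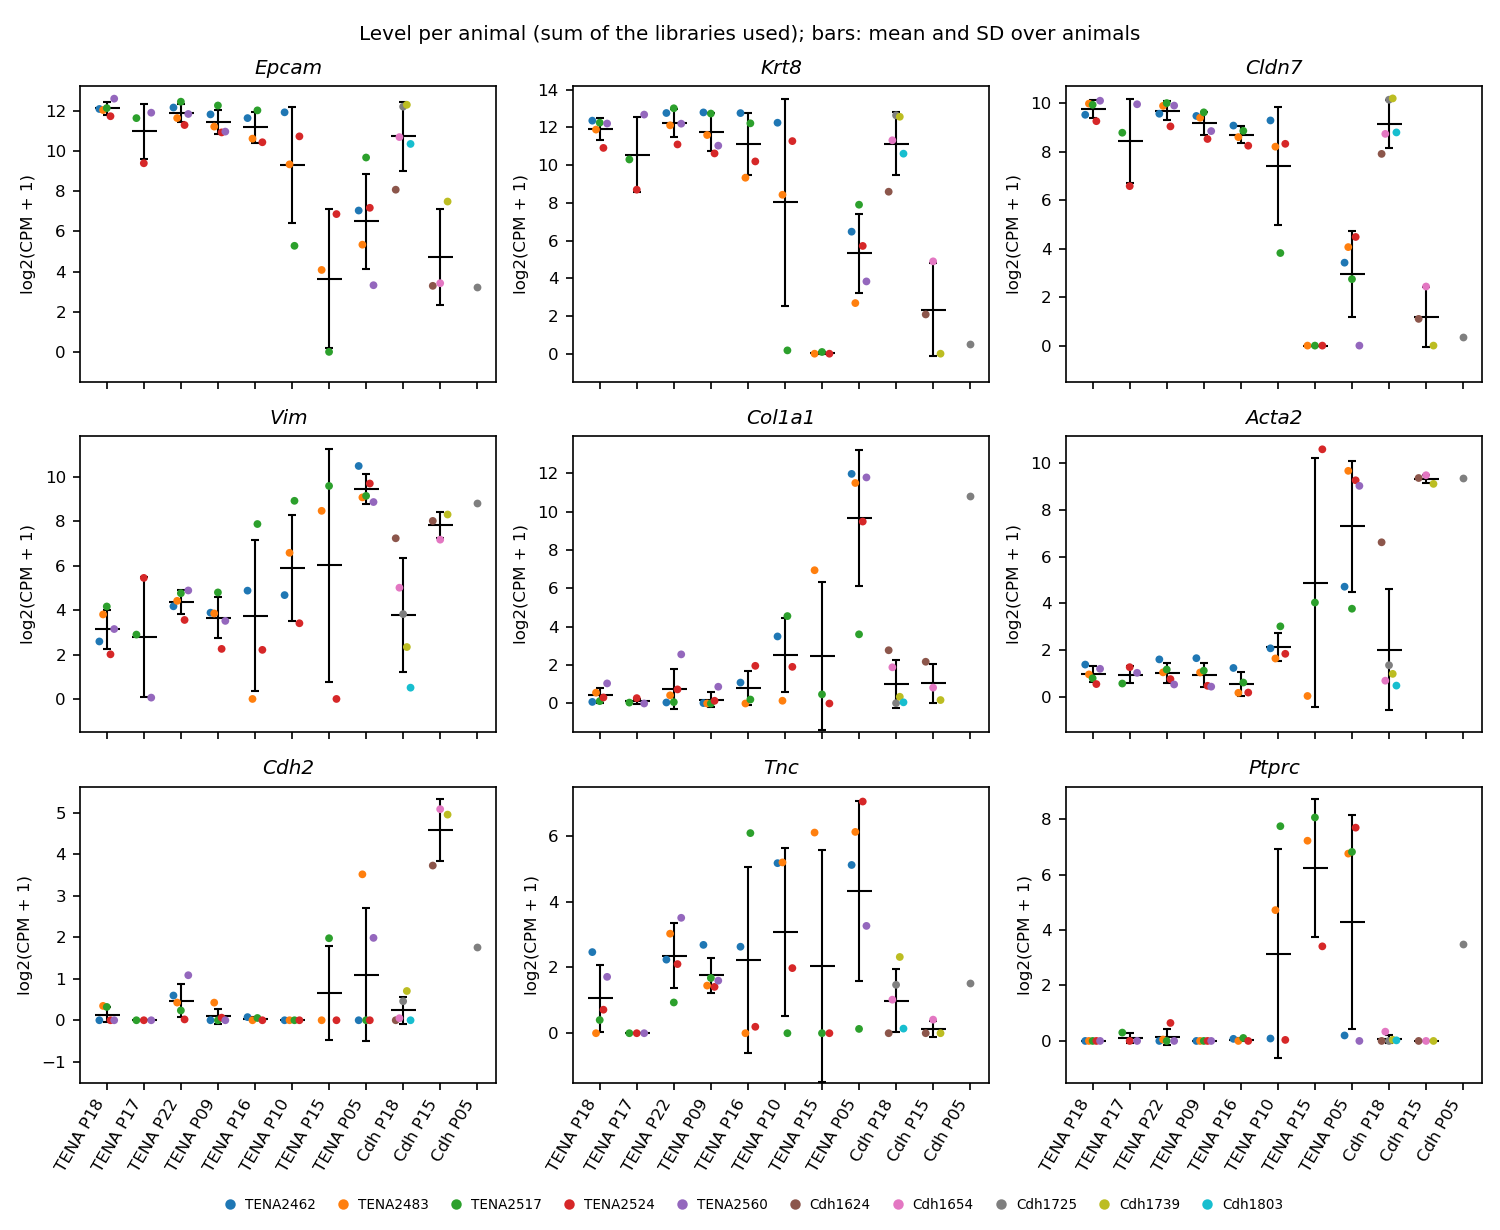
Levels of 9 marker genes as log2(CPM + 1), one point per animal and population. Krt8 and Cldn7 are near 0 in Tnc-CreERT2 P15, where Ptprc averages 141 CPM, and Vim, Col1a1 and Acta2 are highest in EpCAM-negative populations.

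Red cells without surface EpCAM (P05), which had not switched colour, carried a broad programme of extracellular matrix. Col1a1 (chromosome 11, 94936224 to 94953042), the main chain of type I collagen, averaged 2232 ± 1769 CPM against 0.387 ± 0.415 in P18 (log2 fold change 12.89 ± 2.15, adjusted p = 0.0107, higher in 5 of 5 animals). Fbn1 had a log2 ratio of 16.14 (interval 14.29 to 19.19, adjusted p = 0.0232) and Col5a2 a fold change of 11.94 ± 1.83 (adjusted p = 0.0107). Acta2 rose by 8.74 ± 1.65 to 395 ± 359 CPM (adjusted p = 0.0232). Claudins and keratins were lower. Cldn4 had a log2 fold change of -11.42 ± 2.15 (adjusted p = 0.0232), Cldn7 of -6.36 ± 1.28 (adjusted p = 0.0277) and Krt8 of -6.10 ± 1.45 (adjusted p = 0.0463), each lower in 5 of 5 animals. In all, 184 genes were called, 119 higher and 65 lower, with a median over all genes of -0.15. The balance depends on the setting: it was 177 higher and 54 lower with RLE scaling, 801 and 5330 with equal weight of libraries, and 255 and 392 with at least 3 libraries per sum. Without the libraries holding Ptprc it was 123 and 141. A fit of P05 and P18 alone left 2 genes, both higher.

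Of 27 collagen and matrix genes 11 were called higher and 27 were higher over the list alone (median 10.92, adjusted p = 9.34e-28, and 0.0214 with estimated correlation). Mfap5 had a log2 ratio of 17.98 (interval 15.50 to 23.28) and Bgn a fold change of 16.17 ± 2.70, each higher in 4 of 5 animals. Of 26 mesenchymal genes 6 were called and 23 were higher over the list alone (median 7.87, adjusted p = 5.48e-18, and 0.0107 with estimated correlation). Among them were the cadherin Cdh11 (7.18 ± 1.48), Fstl1 (16.36 ± 3.43) and Lox (at least 12.92). Zeb2, a repressor of E-cadherin, averaged 52.8 ± 39.5 CPM against 0.0197 ± 0.0206 (11.13 ± 2.49, adjusted p = 0.0325). With it the EMT transcription factors were higher (4 of 13 over the list alone, median 3.90, adjusted p = 0.0136, and 0.302 with estimated correlation). Partial EMT genes were higher as a list (median 3.29, 7 higher and 2 lower over the list alone, adjusted p = 0.00484, and 0.316 with estimated correlation). Podoplanin Pdpn (11.90 ± 2.38) and Tgfbi (log2 ratio 15.16, interval 12.68 to 20.47) were called. Contractile genes were higher too (3 of 11 over the list alone, median 2.94, adjusted p = 0.0151, and 0.483 with estimated correlation). The basal list was not called (3.71, adjusted p = 0.131) although Acta2 and the Notch ligand Jag2 (at least 11.78) were.

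Markers of stromal cells moved with these genes. Fibroblast markers were higher (5 of 15 called, 12 over the list alone, median 9.68, adjusted p = 2.17e-11, and 0.115 with estimated correlation). Lum was at least 15.24, Col14a1 at least 13.40 and Islr at least 13.17 higher. Macrophage markers were higher (2 of 16 called, 16 over the list alone, median 11.93, adjusted p = 9.16e-14, and 0.151 with estimated correlation). Fcer1g was at 15.66 ± 2.99 and the integrin Itgam at a log2 ratio of 11.93 (interval 9.45 to 17.23). MHC class II (median 5.68, 5 of 7 over the list alone, adjusted p = 0.0315) and endothelial markers (4.70, 3 over the list alone, adjusted p = 0.00485) were higher as lists, with adjusted p = 0.593 and 0.502 with estimated correlation. Without the Ptprc libraries the MHC class II call was lost (0.59, adjusted p = 0.783). Pericyte (4.94, 5.60 with bounds, 4 higher and 1 lower over the list alone, adjusted p = 0.0472) and lymphocyte markers (0.89, 1.24 with bounds, adjusted p = 0.0226) were higher too. Both had adjusted p = 0.521 with estimated correlation. In a fit of P05 and P18 alone the pericyte median turned to -5.99 (adjusted p = 0.188), and to -3.67 (0.179) with quality weights. Of the 32 P05 libraries 16 held Col1a1 and 7 held Ptprc at 10 CPM or more, with 1 library holding both, and 10 held Krt8. Other genes named by the rule were the leukocyte genes Lsp1 (at least 13.92) and Ms4a7 (at least 13.50), the basement membrane gene Nid1 (at least 13.27), Cd34 (at least 13.40), Tmem119 (at least 13.18) and Rcn3 (log2 ratio 15.94, interval 13.46 to 21.24).

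Epithelial genes were lower in P05 (4 of 32 called, 19 over the list alone, median -3.96, adjusted p = 2.18e-23, and 0.0789 with estimated correlation). Besides Cldn4, Cldn7 and Krt8 the called member was Spint1 (-7.95 ± 1.57). Outside the list Prss22 (-11.18 or lower), Fermt1 (-9.67 or lower), Fam83h (-9.22 or lower), the transcription factor Tfcp2l1 (-9.14 or lower), Ankrd22 (-9.94 ± 2.06), the kinase Mapk13 (-9.78 ± 1.57) and Sectm1b (-9.41 ± 2.05) were lower. Milk genes (median -3.48, -3.36 with bounds, 3 lower over the list alone, adjusted p = 0.000104), hypoxia and glycolysis (-0.70, adjusted p = 0.00337) and the interferon response (median -0.74, mean 0.16, tested direction down, adjusted p = 0.00278) were lower as lists. They had adjusted p = 0.335, 0.57 and 0.593 with estimated correlation. Epcam itself fell short of the threshold (-4.76 ± 1.18, adjusted p = 0.056).

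The P05 count depends on single animals: it was 1 without TENA2462, 7 without TENA2483, 86 without TENA2517, 1 without TENA2524, 2 without TENA2560 and 292 without Cdh1725 (286 without Cdh1624). None of the 35 named called genes passed in every such fit. DESeq2 called 4997 genes. Lists that lost their call were the EMT transcription factors (median 2.56, adjusted p = 0.056) and contractile genes (0.0656) without TENA2560, and MHC class II without TENA2483 or TENA2524 (0.128 and 0.0985). Others were hypoxia without Cdh1725 (0.0601), lymphocyte markers without TENA2517 (0.062) and pericyte markers without Cdh1624, Cdh1654, TENA2462 or TENA2483 (0.0606, 0.0525, 0.0712 and 0.0815).

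**Figure D3:**
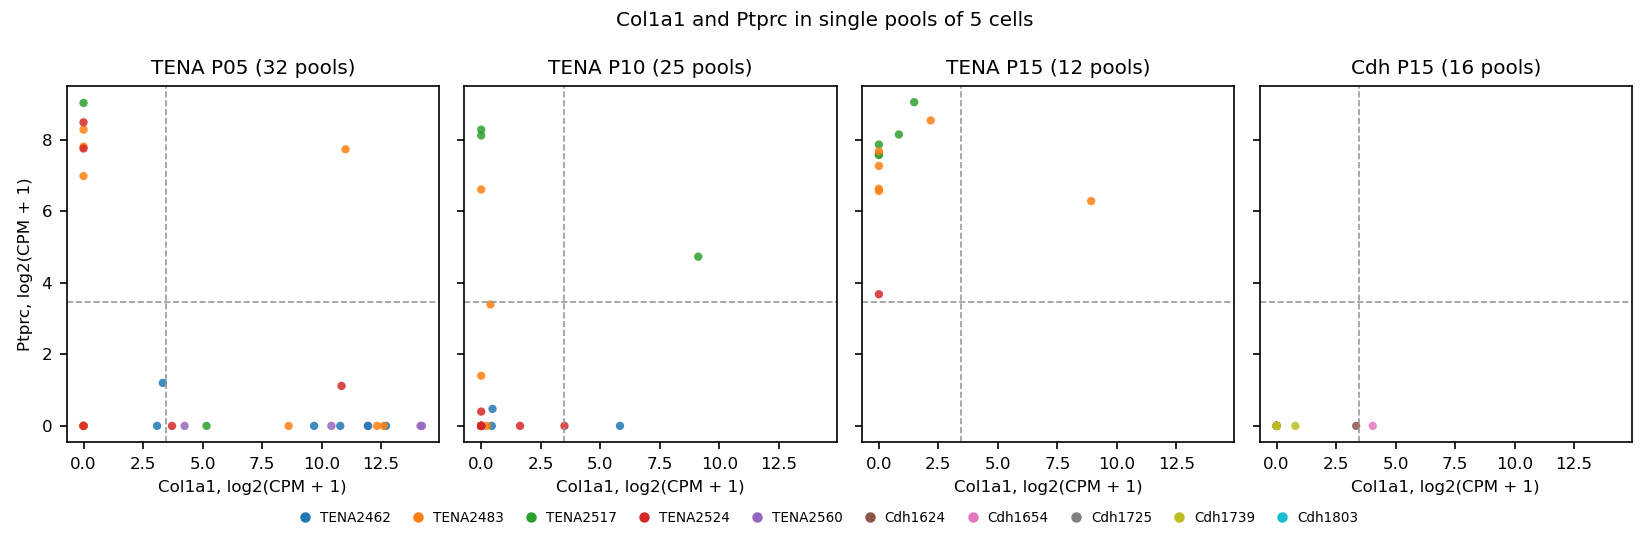
Col1a1 against Ptprc in each 5-cell library of the EpCAM-negative and EpCAM-low populations, in log2(CPM + 1), with dashed lines at 10 CPM. All 12 Tnc-CreERT2 P15 libraries lie above the Ptprc line, 16 of 32 P05 libraries lie above the Col1a1 line with 1 above both, and none of the 16 Cdh2-CreERT2 P15 libraries lies above the Ptprc line.

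Set against each other, the GFP-positive and the mCherry-positive cells without EpCAM differed in both epithelial and matrix transcripts. P15 had less elastin (Eln, log2 ratio -12.84, interval -15.12 to -11.29, adjusted p = 0.0417). The matrix list was lower (median -4.18, adjusted p = 3.72e-24, and 0.00262 with estimated correlation). Of its 27 genes 1 was called and 2 were lower over the list alone. Mesenchymal genes (median -3.25, 2 lower over the list alone, adjusted p = 6.14e-11, and 0.00262 with estimated correlation) and fibroblast markers (-9.81, -7.76 with bounds, 8 of 15 over the list alone, adjusted p = 1.09e-12, and 0.0167 with estimated correlation) were lower in P15. So were EMT transcription factors (-6.61, -5.53 with bounds, adjusted p = 0.000319, and 0.0214 with estimated correlation) and partial EMT genes (-2.06, 1 higher and 3 lower over the list alone, adjusted p = 2.41e-05, and 0.0354 with estimated correlation). Col1a1 averaged 41.0 ± 70.6 CPM in P15 (0.332 without library R3 of TENA2483) and 2232 ± 1769 in P05. Epithelial transcripts found in P05 were lower in P15 as well. In P05 they lay in part of the pools, with Krt8 at 10 CPM or more in 10 of 32 libraries. Plet1 (127 ± 144 CPM in P05) was -10.09 or lower and Ehf -7.67 ± 1.17. Cldn3 was at a log2 ratio of -11.66 (interval -16.97 to -9.19), Spint2 -5.03 ± 1.01 and the water channel gene Aqp5 at -13.17 (interval -18.48 to -10.70). The epithelial list was lower (3 called, 15 over the list alone, median -7.89, -5.64 with bounds, adjusted p = 1.56e-06, and 0.52 with estimated correlation).

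Mitochondrial transcripts were lower in P15 than in P05. The complex I genes mt-Nd1 (742 ± 334 against 4097 ± 1875 CPM) and mt-Nd4 had log2 fold changes of -2.48 ± 0.50 and -2.24 ± 0.47 (adjusted p = 0.0289 and 0.0417). Of the list, 9 of 9 members were lower over the list alone (median -1.98, adjusted p = 1.42e-11, and 0.0789 with estimated correlation). TGF-beta response genes were lower (median -1.41, adjusted p = 1.01e-06, and 0.0151 with estimated correlation). Tgfb2 was called (-6.78 ± 1.42) and 3 lower over the list alone. Contractile genes (-1.65, adjusted p = 0.000231), the interferon response (-4.20, adjusted p = 0.00484) and immediate early genes (-0.86, adjusted p = 0.0121) were lower. The cell cycle (1.76, adjusted p = 0.0375) and lymphocyte lists (2.61, adjusted p = 0.000271) were higher. These 5 lost the call with estimated correlation (adjusted p = 0.158, 0.596, 0.683, 0.742 and 0.316). Macrophage markers did not differ past the threshold (-0.46, adjusted p = 0.159), with Ptprc at 10 CPM or more in 12 of 12 P15 and 7 of 32 P05 libraries. Of 46 called genes 5 were higher, among them Rbm15 (5.88 ± 1.01), and 41 lower. Rbm15 was at 1.66 (adjusted p = 0.593) without TENA2524, and lost its call without TENA2462 or TENA2560 (0.0856 and 0.0534). RLE scaling gave 20 higher and 61 lower, and equal weight of libraries the opposite balance, 80 higher and 40 lower, with 2 genes shared. A fit of P15 and P05 alone called 0 genes, with or without quality weights, and the test of immediate early genes changed direction (adjusted p = 0.66). The lower ones included Plekhb1 (-9.81 or lower), Lurap1l (-9.26 or lower), Tspan12 (-8.72 or lower), Plet1os (-8.70 or lower) and Nqo1 (-8.74 or lower), and the median over all genes was -0.58.

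Without TENA2524 the count of 46 became 3, without TENA2462 11, without TENA2483 125, without TENA2560 13, without Cdh1624 90 and without Cdh1725 71. None of the 15 named called genes passed in every fit (Plet1 had an adjusted p of 0.0895 without TENA2524). DESeq2 called 4513. The calls of TGF-beta genes without TENA2524 (adjusted p = 0.0784), cell cycle genes without TENA2483, TENA2517 or Cdh1624 (0.918, 0.118 and 0.0803), interferon genes without TENA2483 or Cdh1725 (0.499 and 0.0801) and immediate early genes without TENA2524 or Cdh1725 (0.42 and 0.372) were lost.

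GFP-positive cells with low surface EpCAM (P10) differed between animals in their epithelial transcripts. Krt8 was at 10 CPM or more in 7 of 7 libraries of TENA2462 and of TENA2524, 4 of 7 of TENA2483 and 0 of 4 of TENA2517. Cldn7 averaged 312 ± 249 CPM and Cd24a, a surface protein of luminal cells, 290.0 ± 208 CPM (n = 4), against 882 ± 203 and 1003 ± 90.7 in P18, and neither passed alone. The epithelial list was lower (median -1.12, adjusted p = 1.01e-06, and 0.506 with estimated correlation). The interferon response was lower as well (median -2.78, adjusted p = 1.41e-06, and 0.335 with estimated correlation). Isg15 stood at 1.71 ± 1.99 CPM against 18.2 ± 5.77, lower in 4 of 4 animals. Mitochondrial (median -0.92, adjusted p = 4.07e-05) and immediate early genes (-0.53, adjusted p = 0.00393) were lower, without a call under estimated correlation (adjusted p = 0.368 and 0.615). The test of immediate early genes changed direction in a fit of P10 and P18 alone (0.66). Macrophage (median 9.91, 9.65 with bounds, 13 of 16 over the list alone, adjusted p = 0.00146), MHC class II (6.27, 6 of 7 over the list alone, adjusted p = 0.0449) and lymphocyte lists (0.20, 0.51 with bounds, adjusted p = 0.000899) were higher. They had adjusted p = 0.6, 0.613 and 0.335 with estimated correlation. Ptprc was at 10 CPM or more in 4 of 25 P10 libraries. Without them the MHC class II median turned to -0.27 (adjusted p = 0.697). Without animal TENA2517 the macrophage median was 3.17 (adjusted p = 0.162) and that of MHC class II 4.36 (0.209).

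Gm26917 alone was called in P10 against P18 (DESeq2 2454). Annotated as long noncoding RNA (chromosome 17, 39843013 to 39846341), it averaged 1738 ± 804 CPM against 149 ± 88.9 (3.70 ± 0.48, adjusted p = 0.000686, higher in 4 of 4 animals). It was also the only call in P16 against P18 (1874 ± 1100 CPM, 3.65 ± 0.49, adjusted p = 0.000946). The source of its reads was not tested. The P10 call was lost without TENA2462, TENA2517 or TENA2524 (0 genes each) and the count was 2 without Cdh1654, Cdh1739 or Cdh1803. The P16 count was 0 without the same 3 Tnc-CreERT2 animals and 3 without Cdh1624. Both were also lost with all libraries and in fits of the compared populations alone, and the P10 call without the animal block (0 genes each). The MHC class II call in P10 was also lost without TENA2483, Cdh1624 or Cdh1654 (adjusted p = 0.13, 0.0709 and 0.0525), and that of immediate early genes without Cdh1725 or TENA2517 (0.181 and 0.0801). Mesenchymal genes (3.20, adjusted p = 0.0875) and neutrophil markers (adjusted p = 0.0776, the lowest of that list in any comparison) did not pass. The median of all genes was -0.22 in P10 and -0.21 in P16.

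P15 had fewer epithelial transcripts than P10, and Ptprc at 10 CPM or more in 12 of 12 against 4 of 25 libraries. Krt8 went from 1919 ± 2244 CPM in P10 (n = 4) to 1 read (log2 ratio -16.22, interval -21.53 to -13.75, adjusted p = 0.0102). Plet1 was -14.58 or lower (adjusted p = 0.000264), Plet1os -13.10 or lower, and Cldn7 -11.95 or lower. Cldn3 had a log2 ratio of -14.70 (interval -20.00 to -12.22) and Spint2 a fold change of -6.97 ± 1.09. Ehf averaged 0.207 CPM in P15 and 138 ± 113 in P10 (adjusted p = 0.000664). The epithelial list was lower (6 called, 26 of 32 over the list alone, median -11.44, -8.61 with bounds, adjusted p = 1.27e-31, and 0.0326 with estimated correlation). Milk genes were lower too (7 over the list alone, median -8.51, -4.07 with bounds, adjusted p = 2.36e-06, and 0.226 with estimated correlation). Hypoxia (-0.60, adjusted p = 0.0274) and TGF-beta genes (median -0.02, mean -1.30, Tgfb2 at -6.96 ± 1.42 called, 2 over the list alone, adjusted p = 0.0315) were lower, with adjusted p = 0.647 and 0.377 with estimated correlation. Mesenchymal (1.25, 2 higher and 1 lower over the list alone, adjusted p = 0.048), macrophage (1.40, adjusted p = 0.00104) and lymphocyte lists (1.75, adjusted p = 0.0166) were higher. These had adjusted p = 0.377, 0.596 and 0.529 with estimated correlation. Of 75 called genes 68 were lower and 7 higher, among them Dnajc9 (9.28 ± 2.07), Nmt1 (4.56 ± 0.89) and Hnrnpa1 (4.37 ± 0.87), with P15 SDs above their means (651 ± 1024 CPM for Dnajc9). RLE scaling gave 16 higher and 65 lower, and equal weight of libraries the opposite balance, 62 higher and 16 lower, with 5 genes shared. A fit of P15 and P10 alone called 20 genes, and 0 with quality weights, and the tests of hypoxia and TGF-beta genes changed direction (adjusted p = 0.885 and 0.929). DESeq2 called 4393, and the median of all genes was -0.48.

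Plet1, Plet1os and Ehf were the 3 of 11 named genes that passed whichever animal was left out of P15 against P10. The count was 11 without TENA2462, 10 without TENA2524 (Nmt1 then at 1.48, adjusted p = 0.512, and Hnrnpa1 at 1.12, adjusted p = 0.65), 24 without TENA2560 and 132 without Cdh1624. The mesenchymal call was lost without TENA2462, TENA2483, Cdh1624 or Cdh1654 (adjusted p = 0.0814, 0.376, 0.0834 and 0.0563) and that of hypoxia without TENA2462, TENA2524 or Cdh1725 (0.104, 0.291 and 0.191). That of TGF-beta was lost without TENA2462, TENA2483, TENA2524 or Cdh1725 (0.0674, 0.071, 0.831 and 0.28) and lymphocyte markers without TENA2483, TENA2524 or Cdh1725 (0.0729, 0.099 and 0.105).

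P10 and P16, the EpCAM-low and one of the EpCAM-medium GFP-positive populations, differed in 0 genes by edgeR, with 1610 at an unadjusted p below 0.05, 1905 called by DESeq2 and a median of all genes of 0.00. As lists, P10 was lower in epithelial genes (median -0.61, adjusted p = 7.45e-07) and mitochondrial RNA (-0.50, adjusted p = 8.78e-05). It was higher in mesenchymal (1.58, adjusted p = 0.0131), macrophage (9.59, 8.87 with bounds, 7 over the list alone, adjusted p = 2.5e-07), MHC class II (4.17, adjusted p = 0.000309) and lymphocyte genes (0.19, adjusted p = 0.0315). With estimated correlation none held (adjusted p = 0.52, 0.377, 0.57, 0.335, 0.359 and 0.57). Ptprc was at 10 CPM or more in 4 of 25 P10 and 0 of 26 P16 libraries. Without these 4 the MHC class II median turned to -1.93 (adjusted p = 0.516) and the lymphocyte call was lost (0.0845). Without TENA2517 the epithelial (adjusted p = 0.672), macrophage (0.112), lymphocyte (0.272) and MHC class II calls (0.0715) were lost, the last also without TENA2483 (0.1). The mesenchymal call was lost without TENA2483 or TENA2524 (0.206 and 0.0553) and the mitochondrial one without TENA2524 (0.681).

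GFP-positive cells with medium surface EpCAM (P16 and P09) differed from P18 in gene lists more than in single genes called by edgeR. How far they differ gene by gene depends on the tool: in P16 DESeq2 called 1799, voom with quality weights 3826 and equal weight of libraries 291. In P16 interferon response (median -1.16, adjusted p = 2.64e-05), TGF-beta response (-0.82, adjusted p = 0.00435) and immediate early and heat shock genes (adjusted p = 0.00349) were lower. MHC class I genes passed downward despite a mean of 0.30 (median -0.05, adjusted p = 0.0255). Lymphocyte markers were higher (0.04, 0.42 with bounds, adjusted p = 0.0299). In a fit of P16 and P18 alone the tests of MHC class I and immediate early genes changed direction (adjusted p = 0.907 and 0.367). With estimated correlation none of these 5 held (adjusted p = 0.409, 0.196, 0.615, 0.529 and 0.57). Snai1, a repressor of E-cadherin in the TGF-beta list, averaged 13.8 ± 13.2 CPM against 33.1 ± 10.8, lower in 4 of 4 animals. Without TENA2524 the MHC class I, TGF-beta, immediate early and lymphocyte calls were lost (adjusted p = 0.165, 0.0566, 0.107 and 0.062). Without TENA2483 it was those of MHC class I, immediate early and lymphocyte genes (0.127, 0.157 and 0.1). Without Cdh1725 it was those of MHC class I, TGF-beta and immediate early genes (0.0731, 0.0878 and 0.198), without TENA2517 that of MHC class I (0.118) and without TENA2560 that of lymphocyte markers (0.0591).

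P09 cells held more transcripts of dividing cells than P18 and fewer of mitochondria. The proliferation marker Mki67 averaged 12.2 ± 11.1 CPM against 0.862 ± 1.31, higher in 5 of 5 animals. Of the list, 24 of 25 cell cycle genes had positive fold changes (median 1.76, adjusted p = 4.76e-11, and 0.248 with estimated correlation). The cytochrome oxidase gene mt-Co1 stood at 2129 ± 337 CPM against 4670.0 ± 479, lower in 5 of 5 animals. Mitochondrial RNA was lower as a list (6 of 9 over the list alone, median -1.07, adjusted p = 1.27e-31, and 0.00328 with estimated correlation). Immediate early genes (-0.75, adjusted p = 1.68e-07) and erythrocyte markers (-4.05, -2.23 with bounds, 1 over the list alone, adjusted p = 0.00257, or 0.257 without TENA2483) were lower, without a call under estimated correlation (adjusted p = 0.335 and 0.316). EdgeR called 0 genes in P09 against P18 (851 at an unadjusted p below 0.05, DESeq2 1050, median of all genes -0.03).

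P09 and P16 did not differ in any gene by edgeR (0 called, 1683 at an unadjusted p below 0.05, DESeq2 1768, median of all genes 0.18), several lists did. P09 was higher in cell cycle (1.64, adjusted p = 3.94e-09), interferon (0.94, adjusted p = 3.01e-05), MHC class I (0.11, adjusted p = 0.0103), TGF-beta (0.63, adjusted p = 0.0133) and epithelial genes (0.38, adjusted p = 0.0396). It was lower in mitochondrial RNA (-0.76, adjusted p = 0.00104) and lymphocyte markers (-0.67, adjusted p = 0.0156). With estimated correlation none held (adjusted p = 0.316, 0.377, 0.502, 0.309, 0.773, 0.521 and 0.521). The adipocyte list had its lowest adjusted p of any comparison here (0.0743) and was not called. Without TENA2524 the calls of epithelial, MHC class I, TGF-beta, lymphocyte and mitochondrial genes were lost (adjusted p = 0.0849, 0.135, 0.113, 0.0946 and 0.106). Without Cdh1725 it was those of epithelial and TGF-beta genes (0.573 and 0.175), without TENA2483 those of epithelial and lymphocyte genes (0.13 and 0.0846) and without TENA2517 those of epithelial and MHC class I genes (0.0722 and 0.0813).

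Double-positive pools (P22) held low levels of mesenchymal transcripts beside an epithelial profile. Whether 1 cell held both was not tested. Krt8 averaged 5301 ± 2362 CPM, and 23 of 26 mesenchymal genes had positive fold changes (median 1.46, adjusted p = 1.88e-05, and 0.151 with estimated correlation). Partial EMT genes were higher (0.98, adjusted p = 0.000135, and 0.118 with estimated correlation). The basal keratin Krt17 was higher in 5 of 5 animals (182 ± 138 against 60.2 ± 112 CPM). Mitochondrial RNA was lower (median -0.65, adjusted p = 4.81e-19, and 0.0214 with estimated correlation). Interferon (-0.70, adjusted p = 0.000171) and MHC class I genes (-0.21, adjusted p = 0.00986, or 0.143 without TENA2524) were lower and milk genes higher (1.17, adjusted p = 0.0166), without a call under estimated correlation (adjusted p = 0.483, 0.502 and 0.596). The milk call was lost without Cdh1624, Cdh1654, Cdh1739, TENA2483, TENA2517 or TENA2560 (adjusted p = 0.177, 0.0668, 0.0767, 0.197, 0.0606 and 0.338). EdgeR called 0 genes (716 at an unadjusted p below 0.05, DESeq2 914, median of all genes -0.01).

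The mCherry-positive P17 population, EpCAM high like P18, held cells with more cell cycle transcripts and fewer of partial EMT. Mki67 averaged 21.1 ± 1.77 CPM (n = 3) against 0.862 ± 1.31. As in P09, 24 of 25 cell cycle genes had positive fold changes (median 3.74, adjusted p = 1.87e-05, and 0.477 with estimated correlation). Partial EMT genes were lower (-1.84, adjusted p = 0.000864, and 0.0862 with estimated correlation). Plau, the urokinase gene, stood at 0.0692 ± 0.0859 against 3.52 ± 1.58 CPM and Tnc at 0 reads. P17 was higher than P18 in mitochondrial RNA (0.93, adjusted p = 7.78e-08, and 0.211 with estimated correlation). Of its 48 libraries 37 had failed quality control. Lower lists were MHC class I (-1.09, adjusted p = 0.000406), epithelial (-0.76, adjusted p = 0.00257), immediate early (-0.64, 1 lower over the list alone, adjusted p = 0.00329) and milk genes (-1.46, -1.32 with bounds, adjusted p = 0.00379). Also lower were hypoxia (-0.78, adjusted p = 0.0066), TGF-beta (-1.05, adjusted p = 0.0086) and interferon (-0.49, adjusted p = 0.00872). With estimated correlation their adjusted p were 0.302, 0.683, 0.597, 0.521, 0.596, 0.311 and 0.596. Macrophage (3.66, adjusted p = 0.0255) and, by test though not median, lymphocyte markers (-0.95, 0.81 with bounds, adjusted p = 0.0212) were higher. Ptprc was at 10 CPM or more in 0 of 11 libraries. With estimated correlation adjusted p was 0.731 and 0.547. EdgeR called 0 genes (1695 at an unadjusted p below 0.05, DESeq2 1858, median of all genes -0.40).

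In P17 against P18 the calls of epithelial, hypoxia, macrophage and lymphocyte genes were lost without TENA2524 (adjusted p = 0.108, 0.113, 0.33 and 0.0784). Lost without TENA2517 were those of milk, interferon, TGF-beta and immediate early genes (0.162, 0.57, 0.0542 and 0.439), and without Cdh1725 those of interferon, hypoxia, TGF-beta and immediate early genes (0.085, 0.114, 0.106 and 0.0509). The interferon and lymphocyte calls were also lost without TENA2560 (0.0583 and 0.121) and the macrophage call without TENA2483 (0.0678).

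**Figure D4:**
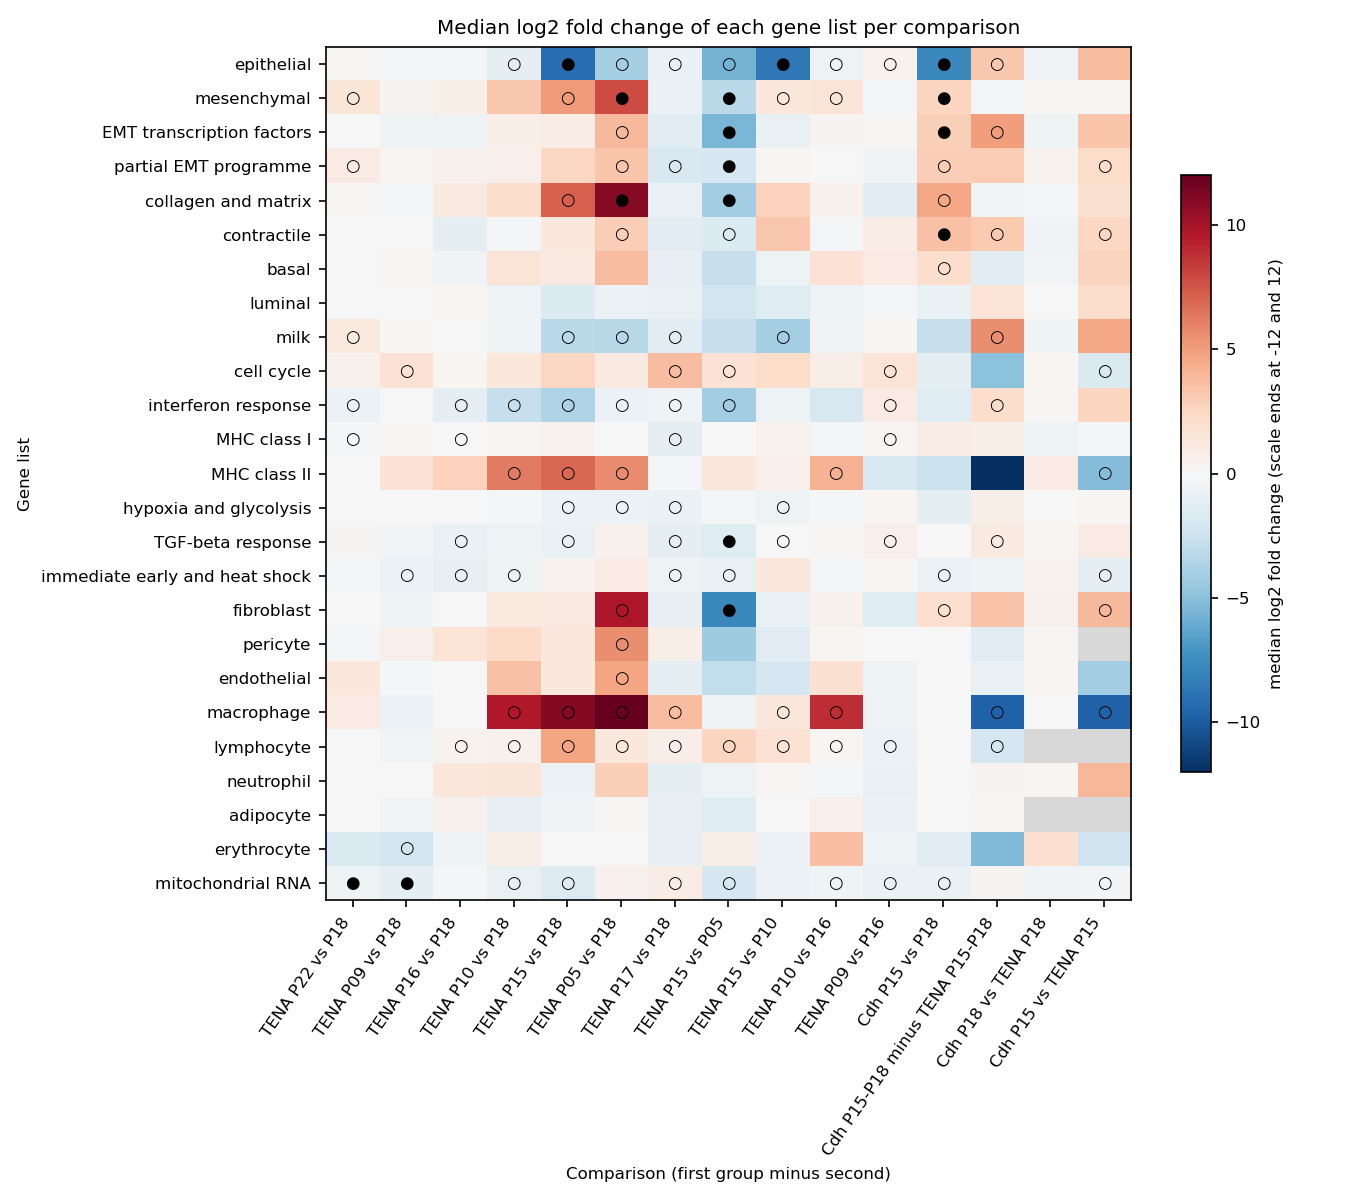
Median log2 fold change per list and comparison, genes at 0 reads at their bound (for the difference of the lines' steps, Cdh2-CreERT2 reads only). Open circles mark lists called by camera, filled circles those also called with estimated correlation, and grey fields lists that were not tested. The epithelial list has filled circles in 3 comparisons of P15.

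In the Cdh2-CreERT2 line, GFP-positive cells without EpCAM (P15) were higher in contractile and mesenchymal gene lists, without the main collagen. Col1a1 was at 10 CPM or more in 1 of 16 libraries. Cdh2 itself (chromosome 18, 16588877 to 16809246) averaged 25.0 ± 11.2 CPM (n = 3) against 0.208 ± 0.283 in P18 (n = 5), higher in 3 of 3 animals (7.98 ± 3.26, adjusted p = 1). Acta2 stood at 638 ± 81.6 against 20.1 ± 42.9 CPM (1.21 without library R8 of Cdh1624), the matrix glycoprotein Sparc at 415 ± 54.8 against 3.27 ± 2.28. Zeb1, a repressor of E-cadherin, was at 40.8 ± 7.48 against 1.28 ± 2.24 and Twist1 at 4.43 ± 0.886 against 0 reads. Cldn7 averaged 1.85 ± 2.29 CPM against 679 ± 434 and Krt8 10.7 ± 15.8 against 3383 ± 2696, and none of these genes passed alone. EdgeR called 0 genes, with 1215 at an unadjusted p below 0.05 and 1752 called by DESeq2, and a median of all genes of 0.00. Of 50 changes of log2 4 simulated with the spread of P18 sums, the fit recovered 12 in this comparison, against 38 in Tnc-CreERT2 P05 and 27 in P15.

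As lists, epithelial genes were lower (20 of 32 over the list alone, median -8.26, -7.72 with bounds, adjusted p = 1.84e-32, and 0.0326 with estimated correlation). Mesenchymal genes (3 over the list alone, median 2.62, adjusted p = 3.67e-11, and 0.0354 with estimated correlation) were higher. So were EMT transcription factors (1 over the list alone, 2.89, adjusted p = 3.25e-05, and 0.0214 with estimated correlation) and contractile genes (4 of 11 over the list alone, 3.56, adjusted p = 4.99e-08, and 0.0413 with estimated correlation). Collagen and matrix (6 over the list alone, 4.65, adjusted p = 2.6e-13) and partial EMT genes (3 higher and 2 lower over the list alone, 2.91, adjusted p = 0.000172) were higher, with adjusted p = 0.161 and 0.115 with estimated correlation. Basal (2 higher and 2 lower over the list alone, 2.15, adjusted p = 0.0121) and fibroblast genes (2 over the list alone, 1.85, 2.00 with bounds, adjusted p = 0.00048) were higher too, with adjusted p = 0.52 and 0.519 with estimated correlation. Members of the basal list parted, with calponin Cnn1 at 160 ± 171 against 0.444 ± 0.994 CPM and Krt14 at 0 reads against 46.3 ± 46.2 CPM. Mitochondrial RNA (-0.80, adjusted p = 6.32e-06) and immediate early genes (-0.74, adjusted p = 0.0277) were lower, again not under estimated correlation (adjusted p = 0.316 and 0.718). Macrophage markers did not differ past the threshold (median 0.00, adjusted p = 0.635), and of 16 P15 libraries 0 held Ptprc, 13 held Acta2, 10 held Cdh2 and 4 held Krt8 at 10 CPM or more. The calls of partial EMT, basal and mitochondrial genes were lost without Cdh1739 (adjusted p = 0.0871, 0.0894 and 0.102). So were that of basal genes without Cdh1624 (0.109) and that of immediate early genes without Cdh1654, Cdh1739 or TENA2560 (0.889, 0.123 and 0.0563).

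The step from P18 to P15 differed between the lines in 3 genes. Nfix, a transcription factor, averaged 183 ± 63.8 CPM in Cdh2-CreERT2 P15 and 99.4 ± 41.0 in P18 of that line, and 1.92 and 85.2 CPM in P15 and P18 of the Tnc-CreERT2 line (difference of log2 fold changes 6.23 ± 1.01, adjusted p = 0.0164). Plekhb1 stood at 205 ± 170 and 174 ± 55.9 CPM against 0 reads and 192 CPM (fitted difference 16.13 ± 2.53, which rests on the 0 reads, adjusted p = 0.0164). The phosphatase gene Pgp stood at 99.1 ± 61.5 and 304 ± 122 against 0.0116 and 213 CPM (11.49 ± 1.98, adjusted p = 0.0321). All 3 kept their level in Cdh2-CreERT2 P15 better than in Tnc-CreERT2 P15, and 2342 genes had an unadjusted p below 0.05 (DESeq2 called 3305, median of all genes 0.69). The count was 0 without TENA2462, TENA2524 or Cdh1624, 1 without Cdh1654 or Cdh1739, 5 without Cdh1725 or Cdh1803, 49 without TENA2483 and 24 without TENA2517. RLE scaling and fits of the compared populations alone gave 0. All libraries (2 genes) and voom with quality weights (4 genes) called none of them.

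As lists, macrophage (median -11.72, 1 over the list alone, adjusted p = 2.43e-05) and lymphocyte genes (-5.93, adjusted p = 0.0003) were lower in the Cdh2-CreERT2 step. Interferon (2.14, adjusted p = 0.00329), contractile (3.11, 1 over the list alone, adjusted p = 0.00485) and TGF-beta genes (1.11, 2 over the list alone, adjusted p = 0.00518) were higher. So were epithelial (3.24, 4 over the list alone, adjusted p = 0.0113), milk (5.61, 4 over the list alone, adjusted p = 0.0317) and EMT transcription factor genes (5.05, adjusted p = 0.046). With estimated correlation none held (adjusted p = 0.502, 0.316, 0.57, 0.335, 0.244, 0.718, 0.615 and 0.355). Single animals ended 5 of these calls. They were epithelial without Cdh1624, Cdh1654, Cdh1725 or TENA2483 (0.251, 0.0581, 0.295 and 0.066), interferon without Cdh1624, Cdh1725 or TENA2483 (0.11, 0.069 and 0.0531) and TGF-beta without Cdh1725 or TENA2524 (0.112 and 0.0889). Another was milk without Cdh1654, Cdh1725, Cdh1739, TENA2462, TENA2483 or TENA2517 (0.0802, 0.19, 0.0731, 0.0525, 0.108 and 0.0553). The EMT transcription factor call was lost without Cdh1654, Cdh1725, Cdh1739 or Cdh1803 (0.0667, 0.324, 0.219 and 0.0502) and without TENA2462, TENA2483, TENA2517 or TENA2524 (0.0785, 0.117, 0.121 and 0.0726).

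The mCherry-high P18 cells of the 2 lines did not differ in any gene by edgeR (430 of 17878 at an unadjusted p below 0.05, DESeq2 3 genes, median of all genes -0.15) or in any list. The lowest adjusted p of a list was 0.0559 for immediate early genes (median 0.39). P15 cells of the lines likewise differed in 0 genes by edgeR (1485 of 14028 at an unadjusted p below 0.05, DESeq2 1331, median of all genes 0.38). As lists, Cdh2-CreERT2 P15 was lower in macrophage (median -9.66, 7 of 8 over the list alone, adjusted p = 9.22e-10), MHC class II (-5.23, 2 over the list alone, adjusted p = 2.07e-05) and cell cycle genes (-1.71, adjusted p = 1.01e-06). It was also lower in immediate early (-1.05, adjusted p = 0.000271) and mitochondrial genes (-0.36, adjusted p = 0.0318). It was higher in contractile (2.53, 1 over the list alone, adjusted p = 0.00872), fibroblast (3.86, 1 over the list alone, adjusted p = 0.0185) and partial EMT genes (2.17, 3 over the list alone, adjusted p = 0.0431). With estimated correlation none held (adjusted p = 0.302, 0.424, 0.605, 0.57, 0.731, 0.576, 0.52 and 0.521). Cd74, the MHC class II invariant chain, averaged 1.65 ± 2.41 against 4792 ± 4190 CPM. Ltbp1, a binding protein of latent TGF-beta, averaged 269 ± 55.0 against 0.358 ± 0.620. Lines and lanes coincide in these comparisons except for TENA2524. The call of partial EMT genes was lost without Cdh1654, Cdh1739, TENA2483, TENA2517 or TENA2524 (adjusted p = 0.0917, 0.388, 0.173, 0.158 and 0.178). That of fibroblast genes was lost without Cdh1624, Cdh1654, Cdh1739, TENA2517 or TENA2524 (0.155, 0.125, 0.243, 0.672 and 0.0784). That of mitochondrial genes was lost without Cdh1624, Cdh1654 or TENA2517 (0.312, 0.076 and 0.387) and that of immediate early genes without TENA2517 (0.0863).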

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

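The tests of other splits of the samples were chosen only after the results were seen. A gap test screened single animals in groups of 4 or 5 (gap of an extreme to its neighbour over the range). Of 157 values 31 stood apart. Reads in only 1 animal fix the gap at 1.0, so the chance rate of 1 in 20 does not apply.

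In P18 the highest animal stood apart for genes near 0 reads there: a gap of 1.0 for Bgn, Fcer1g, Itgam, Laptm5, Mfap5, Mrc1, Pdpn, Rasa4, Rcn3, Tgfbi and Wnt4, and 0.747 for Col5a2. The lowest P18 animal stood apart for Fam83h (0.798), Sectm1b (0.779) and Plekhb1 (0.817), and in the Cdh2-CreERT2 line animal Cdh1624, whose P18 sum holds 879259 counts, was lowest for Pgp (0.787) and Plekhb1 (0.901). In P05 animal TENA2524 was highest for Ankrd22 (1.0), Spint1 (0.861) and mt-Nd1 (0.975), TENA2462 for Cldn4 (0.94) and TENA2517 for Mapk13 (1.0), and TENA2517 was lowest for the matrix genes Bgn (0.761), Eln (0.862) and Mfap5 (0.724). In P10 TENA2517 was lowest for Cldn3 (0.888) and Spint2 (0.933) and TENA2524 highest for Dnajc9 (1.0). In P09 Cdh2 (0.853) was highest in TENA2483 and Tnc (0.789) in TENA2462, and the mitochondrial share of counts in P16 (0.923) in TENA2524.

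The step from P18 to P15 differed between the lines by a test of the difference itself, for Plekhb1 (16.13), Pgp (11.49) and Nfix (6.23), and for the lists of epithelial (3.24), EMT transcription factor (5.05), contractile (3.11), milk (5.61), interferon response (2.14), TGF-beta response (1.11), macrophage (-11.72) and lymphocyte genes (-5.93). None of these lists held with an estimated correlation (adjusted p = 0.244 to 0.718). Outside the libraries compared, the fullest empty well held 256675 counts over 1348 genes and the deepest library that failed quality control 6695416 counts.

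Counts of called genes were set against 21 drawn splits of the same sums into groups of the same sizes, the real one included, in fits of the compared populations alone. The samples are paired, and the real split parts every pair of sums of 1 animal. For P15 against P18 (122 genes, highest other 35) and for P05 against P18 (2 genes, highest other 0), 1 of 21 splits, the real one, gave as many, the smallest share that 21 splits allow. This does not exclude chance, as only 1 other drawn split parts as many pairs in each comparison. These gave 0 genes, and are too few for a share under 0.05. Nor can chance be excluded for P15 against P10 (20 genes, highest other 28), where 3 of 21 splits gave as many. There 4 of the others part as many pairs, the highest of them with 20 genes.

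With 0 genes in the real split, 21 of 21 splits gave as many for P22, P09, P17, P16 and P10 against P18, P15 against P05, P10 against P16, P09 against P16, Cdh2-CreERT2 P15 against P18 and P18 between lines. The highest other was 2065 for P16, 213 for P10, 2431 for P09 against P16 and 11 for Cdh2-CreERT2 P15. It was 0 for the rest. The fits block on the animal, so these counts come from the pairs that a split parts. The splits with 2065 and 2431 genes part TENA2483 alone, whose P16 is 1 library, and that with 213 genes TENA2517 alone. Those with 11 genes part Cdh1654 and Cdh1739. Such counts are the difference between populations in 1 or 2 animals, and differ from the 0 of the real split, which parts all pairs. For the difference between the lines in the step from P18 to P15 (0 genes, highest other 1) and for P15 between lines (0 genes, highest other 0) the 10 splits are too few for a share under 0.05.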

How the results depend on the processing

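The fits without libraries at 10 CPM or more of Ptprc, with a stricter filter, and with quality weights in groups-only fits were chosen only after the results were seen. Of the counts of called genes under other settings 161 moved by more than 1.5 times and 169 did not. Of named gene values 1531 were the same, 578 lost the call and 1 reversed, and of list results 2033, 344 and 34. Lists were not tested under DESeq2 or single libraries. Without the Ptprc libraries no value was had for Tnc-CreERT2 P15 or for the 2 comparisons between lines that use it. The cause was not tested for any reversal.

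Counts below stand for the comparison named, in the Tnc-CreERT2 line unless said otherwise, and "the line difference" is that of the step from P18 to P15. DESeq2 gave 914 for P22, 1050 for P09, 1799 for P16, 2454 for P10, 4941 for P15, 4997 for P05 and 1858 for P17 against P18. It gave 4513 for P15 against P05, 4393 for P15 against P10, 1905 for P10 against P16, 1768 for P09 against P16 and 1752 for Cdh2-CreERT2 P15. Across lines it gave 3305 for the line difference, 3 for P18 and 1331 for P15 between lines. RLE normalization moved the median log2 fold change of all genes by more than 0.1 in P16 (-0.21 to 0.07), P10 (-0.22 to 0.11), P15 (-0.61 to -0.18), P05 (-0.15 to 0.17) and P17 (-0.40 to -0.25) against P18. It did so in P09 against P16 (0.18 to 0.02), the line difference (0.69 to 0.26) and P18 between lines (-0.15 to -0.01). RLE normalization gave 81 for P15 against P05 and 0 for the line difference. No filter gave 2 for P10, 1 for P10 against P16, 2 for Cdh2-CreERT2 P15, 6 for the line difference and 73 for P15 between lines. The stricter filter gave 735 for P15, 396 for P05, 2 for P10, 165 for P15 against P05, 209 for P15 against P10, 1 for P10 against P16, 9 for Cdh2-CreERT2 P15 and 62 for the line difference.

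All libraries whatever their quality label gave 715 for P15, 492 for P05, 0 for P16 and P10, 90 for P15 against P05, 136 for P15 against P10 and 94 for Cdh2-CreERT2 P15. At least 3 libraries per sum gave 2 for P09, 4 for P16, 20 for P10, 647 for P05, 96 for P15 against P05, 131 for P15 against P10, 8 for Cdh2-CreERT2 P15 and 28 for the line difference. Without the Ptprc libraries Cdh2-CreERT2 P15 had 4. Equal weight of libraries gave 1 for P22, 291 for P16, 2545 for P10, 4706 for P15, 6131 for P05, and 14 for P17. It gave 120 for P15 against P05, 1 for P10 against P16, 1419 for Cdh2-CreERT2 P15, 1924 for the line difference and 299 for P15 between lines.

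Single libraries as samples, which treat libraries of an animal as partly independent, gave 355 for P22, 1333 for P09, 9764 for P16, 12555 for P10, 9976 for P15, 13576 for P05, and 1796 for P17. They gave 2503 for P15 against P05, 2574 for P15 against P10, 952 for P10 against P16, 7511 for P09 against P16. In the other line and across lines they gave 5095 for Cdh2-CreERT2 P15, 4361 for the line difference, 4 for P18 and 1209 for P15 between lines. Voom with quality weights gave 139 for P22, 513 for P09, 3826 for P16, 7287 for P10, 3393 for P15, 10629 for P05, and 643 for P17. It gave 638 for P15 against P05, 882 for P15 against P10, 44 for P10 against P16, 1587 for P09 against P16 and 67 for Cdh2-CreERT2 P15. Without the replicate block, unlike the paired fit, the counts were 3 for P16, 0 for P10, 1012 for P15, and 510 for P05. They were 211 for P15 against P05, 244 for P15 against P10, 2 for P10 against P16, 2 for P09 against P16, 22 for Cdh2-CreERT2 P15 and 78 for the line difference. Groups-only fits gave 0 for P16 and P10, 122 for P15, 2 for P05, 0 for P15 against P05, 20 for P15 against P10 and 0 for the line difference. With quality weights they gave 83 for P09, 116 for P16, 1376 for P15, 1023 for P05, 0 for P15 against P05 and P15 against P10, 5 for P09 against P16, 1 for Cdh2-CreERT2 P15 and 0 for the line difference.

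Leaving out 1 animal at a time gave 0 to 0 genes for P22, 0 to 1 for P09, 0 to 3 for P16, 0 to 2 for P10, 42 to 409 for P15, 1 to 292 for P05, and 0 to 1 for P17. It gave 3 to 125 for P15 against P05, 10 to 132 for P15 against P10, 0 to 1 for P10 against P16, 0 to 2 for P09 against P16, 0 to 7 for Cdh2-CreERT2 P15, 0 to 49 for the line difference and 0 to 0 for P18 and P15 between lines.

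Reversed list medians, by the direction of the test, were these in groups-only fits: MHC class I -0.28 and immediate early -0.99 in P16, immediate early -1.05 in P10, and pericyte -5.99 in P05. Others were immediate early -1.18 in P15 against P05, hypoxia -0.46 and TGF-beta -0.31 in P15 against P10, and epithelial 0.39 in P09 against P16. With quality weights added they were MHC class I -0.16 and immediate early -0.24 in P16, epithelial -0.05 and immediate early 0.09 in P10, and pericyte -3.67 in P05. Others were immediate early 0.02 in P15 against P05, hypoxia 0.20 and TGF-beta 0.11 in P15 against P10, epithelial 0.08 in P10 against P16, and interferon -0.24 and MHC class I -0.21 in P09 against P16. Equal weight of libraries reversed contractile 0.09 in P15 against P05 and hypoxia -0.12 and TGF-beta 0.49 in P15 against P10. The stricter filter reversed immediate early -0.83 in P15 against P05, epithelial 0.29 in P09 against P16 and epithelial 3.54 in the line difference, and at least 3 libraries per sum immediate early -0.15 in P15 against P05. Without the Ptprc libraries MHC class II was -0.27 in P10, 0.59 in P05 and -1.93 in P10 against P16. Leaving out 1 animal at a time gave medians of -1.97 to 0.11 for immediate early and 0.97 to 2.60 for cell cycle in P15 against P05. It gave -1.18 to 0.26 for hypoxia and -0.82 to 0.49 for TGF-beta in P15 against P10, and -1.52 to 0.43 for immediate early in Cdh2-CreERT2 P15. The reversals were those without TENA2524 (0.11, 0.26 and 0.49), TENA2483 (0.97) and Cdh1654 (0.43). Single libraries reversed Rbm15 in P15 (-0.82).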

Other observations

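Of the tests below, those of leukocyte RNA in P15 and in P05 and of depth as the whole cause were chosen only after the result was seen. Tnc-CreERT2 P15 carried Ptprc at 141 ± 128 CPM (n = 3 animals) and Acta2 at 516 ± 880, the latter mostly from 1 library of TENA2524. Cdh2-CreERT2 P15 carried Acta2 at 638 ± 81.6 and Cdh2 at 25.0 ± 11.2 CPM, and edgeR called 0 genes between these groups (1485 at an unadjusted p below 0.05, DESeq2 1331). P05 of animal Cdh1725, the 1 Cdh2-CreERT2 animal with this population, held Col1a1 at 1804 CPM, Sparc at 2412, Acta2 at 662, Apoe at 7296, Lyz2 at 1100, Cd74 at 939 and Ptprc at 10.4. Krt8 was at 0.427 (95% counting interval 0.271 to 0.641). Of its 10 libraries 2 held Col1a1 at 10 CPM or more and 2 others Ptprc. Without library R8 Col1a1 was at 168 and Sparc at 774, without R11 Acta2 at 370.5, and without R5 Apoe at 1490, Lyz2 at 303, Cd74 at 6.83 and Ptprc at 2.04. No test was made.

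Macrophage genes were high in the Tnc-CreERT2 P15 pools. With leukocyte RNA as the cause, most macrophage genes should appear together. Of the 12 libraries 6 held 8 or more of the 16 at 10 CPM or more. Pools of other leukocytes would fail this test. Ptprc, at that level in 12 of 12, goes with leukocyte RNA. Tumour cells past the transition that express these genes should keep transcripts common to P18 and Cdh2-CreERT2 P15. Of 611 such genes 0.49 and 3.27 percent were under 1 CPM in the 2 sums of several libraries. This decides nothing, since such broadly expressed genes were kept in nearly all populations. Sorting on a tumour cell reporter should remove leukocytes, unchecked for lack of reporter sequences. The 2 explanations cannot be told apart.

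Collagen and fibroblast genes were high in the Tnc-CreERT2 P05 pools. Leukocyte RNA is left open. The matrix list's median log2 fold change was 10.8 without the Ptprc libraries, but 15 of 16 with Col1a1 lacked Ptprc. Cd74 reached 10 CPM in 13 libraries, Ptprc in 7. Fibroblast RNA would bring other such markers, and of 16 libraries with Col1a1 11 (68.8 percent) held 8 or more of 15 fibroblast genes. Tumour cells past the transition without the colour switch would keep the 611 common genes. Of these 0.16 percent were under 1 CPM in the median sum, which decides nothing as above. Sorting should remove fibroblasts too, again unchecked. Fibroblast RNA and tumour cells cannot be told apart, as the share lies between its limits (25 and 75 percent).

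Fewer genes were detected in P15 and P05 than in P18. Lower sequencing depth as the whole cause is argued against in both, as at 500000 counts per library a gap of 5651 ± 1240 genes (n = 3 animals) remained in P15 and of 5182 ± 1231 (n = 5) in P05. These are 70.6 and 76.9 percent of the full gaps. With a limit of 75 percent set beforehand, how much depth adds stays open in P15. A few genes taking most of the counts are argued against in both, as 90.9 and 91.6 percent of the relative gap remained without the 50 highest genes. No biological explanation was tested.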
